A study of Homo sapiens with 8 samples.

How the data were processed

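Total RNA of NCH644 glioblastoma cells in neurosphere culture was collected 24 h after DMSO, OTX015, panobinostat or both drugs were added, each drug at 5 µM, per the labels' protocols. RNA was labelled with biotin for single-colour expression arrays, per the same protocols. The array model and the probe set definition file are not given in the sources used here. The series text calls the arrays biological duplicates and does not say how the duplicates were separated. Groups and replicate numbers were taken from the sample titles, which gave 4 groups of 2 arrays. The table covered all 8 arrays, 0 of its columns were left unassigned, and 0 pairs of arrays held identical values.

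The deposited values were on a log2 scale and had been made with RMA in affy 1.36.1 under R 2.15.1, per the submitters' processing notes. RMA by default corrects the background, makes array distributions equal and summarises the probes of a probe set, but the notes give only its name and no filter. Array medians over the probe sets with a gene symbol ranged from 3.87 to 4, so the deposited arrays were close to a common scale without being identical in distribution. Because RMA forces a common distribution before summary, a change in the total amount of RNA per cell would not be visible in these values, and signals near background or near saturation are compressed.

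The table held 23786 probe sets. The platform annotation paired 22458 of them with exactly 1 gene symbol, 0 with several, and did not list 1328, which stay unnamed and were tested only as an alternative and as a separate count. No gene had more than 1 probe set, so each of the 22458 genes had 1 value per array. All 22458 symbols were found by gene identifier in a RefSeq gene table, which was used for gene types only. No coordinates are printed, because no genome build is stated for the array.

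All 8 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3) with 4 group means and no covariate, so that the groups shared 1 estimate of the spread, with 4 residual and 4.41 prior degrees of freedom. Comparisons were tested two-sided with lmFit and eBayes for OTX015 against DMSO, panobinostat against DMSO, the combination against DMSO, against OTX015 and against panobinostat, OTX015 against panobinostat, and the interaction (combination minus OTX015 minus panobinostat plus DMSO). P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at adjusted p under 0.05 with no filter on low values. The groups, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined.

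Of 47 gene lists fixed in that way, 46 had at least 5 measured members and were tested with camera at the preset correlation of 0.01, adjusted over the lists of a comparison. Camera compares a list with the other genes. It was run again with the correlation estimated per list, and 0 lists were called in any comparison. Fry, a self-contained directional test that asks whether the genes of a list move on balance one way and does not compare them with other genes, called 23, 41, 42, 34, 20, 34 and 23 lists in the order of the comparisons above. Members were also counted with p-values adjusted over the list alone. A further 4 lists held markers of other cell types.

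The text names, in each comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap between groups (5 and 5 for the interaction), up to 4 called members of each described list with the largest changes, and a fixed set that includes MYC, HEXIM1, CDKN1A, DDIT3 and SOX2 whatever the result. Symbols of uncharacterised loci and small RNAs were left out of the first group. Some genes picked or listed by the rule are not reported here. Overlap between comparisons that share the 2 vehicle arrays was set beside 50 simulations of unchanged groups and beside independent lists. After the data were seen it was also computed with 1 vehicle array for each comparison of a pair, in both assignments. Where the dimmer group of a named gene averaged under the background level of 3.03 (from 352 olfactory receptor genes), the lower bound of its fold was the brighter group's mean against that level, a step also added after the data were seen. The procedure was tested on 3 simulated sets built on the OTX015 and DMSO groups, with 200 of 22458 genes changed in each. It recovered 84.3% of genes changed by 1 on the log2 scale and 99.7% of genes changed by 2, and 6.74% of its calls were unchanged genes. A shifted list was called in 3 of 3 sets with either correlation, and 0 of 135 unshifted ones were. This does not test the preset correlation on real lists.

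Alternatives were centring of each array on its median, quantile normalization, leaving out the lowest 25% of genes, testing all probe sets, fitting only the groups compared, an intensity trend with robust moderation, array weights, the replicate number as a block, adjusted p under 0.01, a minimum log2 change of 1, and leaving out each array in turn. On gene lists, 13 alternatives were run with the preset correlation. Reruns of the counts of genes by how the treatments compare, of unlisted probe sets and of symbol-stem families were added after the data were seen. Any lone array was assumed to vary like the other groups. Taking the mean of a gene's probe sets was planned and not run, since each gene has 1. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.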

Results

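The series profiled gene expression in NCH644, a glioblastoma line with stem-like properties grown as neurospheres, after 24 h with DMSO as vehicle, OTX015, panobinostat or both drugs together. OTX015 is an inhibitor of the BET bromodomain proteins, which bind acetylated histones, and panobinostat is an inhibitor of histone deacetylases (HDACs). Each drug was given at 5 µM, alone or in the combination. Each of the 4 groups held 2 arrays, described by the submitters as biological duplicates, so 8 arrays were compared. The number of arrays limits the precision of every value given here. Array medians over the 22458 named genes lay between 3.87 and 4 on the log2 scale. Duplicates correlated across genes at r = 0.9903 for DMSO, 0.9928 for OTX015, 0.993 for panobinostat and 0.9914 for the combination, and the first principal component carried 68.1% of the variance. Values beside gene symbols are log2 fold changes ± standard error (SE) from limma, with n = 2 arrays in each group. The background level was set at 3.03, the 95th percentile of the group means of 352 olfactory receptor genes. Between 9.9% and 17.4% of the genes called in a comparison averaged under it in at least 1 of the groups compared. Changes of such genes depend on a level that the array did not measure above background, so their folds are given as lower bounds (at least) against that level. In each of the 6 comparisons between groups, both arrays of one group lay beyond both arrays of the other for every gene that passed adjusted p under 0.05, an arrangement that chance gives to 33.3% of genes.

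The first comparison asked what BET inhibition alone did. OTX015 lowered RLBP1, which encodes a retinaldehyde-binding protein, by 22.6-fold (-4.5 ± 0.14, adjusted p = 7.44e-06), the largest fall among genes called for OTX015. The phospholipid-flippase gene ATP10B (-4.07 ± 0.18), the carbonic anhydrase gene CA14 (-4.05 ± 0.26), the chitinase-like gene CHI3L2 (-3.79 ± 0.16), NAV3 (-3.64 ± 0.16) and the transcriptional repressor gene ZHX2 (-3.45 ± 0.19) also fell. The histone genes H2BC5 (2.89 ± 0.18) and H4C4 (2.53 ± 0.30) rose. So did the hyaluronidase gene CEMIP2 (2.67 ± 0.15), the immediate early transcription factor gene EGR1 (2.5 ± 0.25), the formin gene FMN2 (2.39 ± 0.20) and the ephrin gene EFNB2 (2.36 ± 0.18). HEXIM1, an inhibitor of the elongation factor P-TEFb known to rise with BET inhibitors, increased 2.93-fold (1.55 ± 0.17, adjusted p = 0.000805). Camera called neither the list of such genes nor the histone list. H4C4 and FMN2 averaged under the background level in DMSO and ZHX2 under OTX015, which left changes of at least 4.2-fold, 3.2-fold and 6.85-fold. The growth-promoting transcription factor gene MYC fell 2.1-fold (-1.07 ± 0.12, adjusted p = 0.000809). In all, 3697 of 22458 genes passed, 1791 higher and 1906 lower.

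Of 45 measured MYC targets in ribosome biogenesis and growth, 0 were higher and 21 lower, with 1 higher and 30 lower adjusted over the list alone (camera, adjusted p = 2.6e-10, and adjusted p = 0.114 with an estimated correlation). Among them were the folate carrier SLC19A1 (-1.71 ± 0.15), the RNA polymerase III subunit gene POLR3G (-1.38 ± 0.13) and the ribosome-biogenesis gene TCOF1 (-1.27 ± 0.15). Targets of NRF2, the regulator of the oxidative stress response, went the other way: 13 of 21 rose and 0 fell, with 15 higher and 0 lower adjusted over the list alone (camera, adjusted p = 4.83e-09, and adjusted p = 0.336 with an estimated correlation). They included SRXN1 (1.55 ± 0.16), NQO1 (1.47 ± 0.17), TXNRD1 (1.4 ± 0.14) and SQSTM1 (1.34 ± 0.13). Autophagy and lysosome genes had 13 of 32 higher and 0 lower, with 18 higher and 2 lower adjusted over the list alone (camera, adjusted p = 9.97e-06, and adjusted p = 0.114 with an estimated correlation). Among them were the lysosomal cholesterol transporter NPC1 (1.09 ± 0.13) and the sialidase NEU1 (1.01 ± 0.14). Genes known to rise with HDAC inhibitors were raised by the BET inhibitor too, 10 of 18 higher and 1 lower, with 12 higher and 1 lower adjusted over the list alone (camera, adjusted p = 6.68e-06, and adjusted p = 0.114 with an estimated correlation). CDKN1A, a cyclin-dependent kinase inhibitor and p53 target, rose 4.57-fold (2.19 ± 0.13) and TXNIP, a thioredoxin inhibitor, by 1.89 on the log2 scale.

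Of 24 p53 targets, 11 rose and 1 fell, with 13 higher and 1 lower adjusted over the list alone (camera, adjusted p = 5.39e-05, and adjusted p = 0.114 with an estimated correlation). TP53INP1 rose (1.5 ± 0.20) and the nuclease gene AEN fell (-1.16 ± 0.12). Of 7 genes for inhibitors of cyclin-dependent kinases, 4 rose and 0 fell, with 4 higher and 0 lower adjusted over the list alone (camera, adjusted p = 0.00039, and adjusted p = 0.114 with an estimated correlation). The list known to rise with HDAC inhibitors also holds 3 of these 7, of which 2 passed. Among the genes that rose were CDKN2D (1.09 ± 0.18) and CDKN2B (0.98 ± 0.17). In the cell cycle lists, 10 of 49 G2/M and mitosis genes were lower and 1 higher, with 13 lower and 1 higher adjusted over the list alone (camera, adjusted p = 0.000647, and adjusted p = 0.509 with an estimated correlation). Their median was -0.25. FOXM1, a transcription factor of mitotic genes, fell by 2.27-fold (-1.19 ± 0.12). G1/S and DNA replication genes had 13 of 45 lower and 1 higher, with 15 lower and 2 higher adjusted over the list alone (camera, adjusted p = 0.00121, and adjusted p = 0.436 with an estimated correlation). These included E2F8 (-1.46 ± 0.22) and the replication licensing gene CDT1 (-0.98 ± 0.14). Oligodendrocyte lineage genes had 6 of 19 lower and 0 higher, with 8 lower and 0 higher adjusted over the list alone (camera, adjusted p = 0.000608, and adjusted p = 0.114 with an estimated correlation). The largest were in the transcription factors MYRF (-1.82 ± 0.16) and SOX10 (-1.77 ± 0.21). Immediate early genes were mixed, 10 of 20 higher and 3 lower, with 11 higher and 4 lower adjusted over the list alone (camera, adjusted p = 0.0065, and adjusted p = 0.531 with an estimated correlation). The nuclear receptor gene NR4A1 was among those that fell (-2.0 ± 0.13). Hypoxia response genes had 7 of 21 higher and 1 lower, with 10 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.00687, and adjusted p = 0.189 with an estimated correlation). The glucose transporter SLC2A3 rose most (2.17 ± 0.21). Genes known to fall with BET inhibitors, of which the G1/S list also holds 4, had 3 of 14 lower and 0 higher, with 4 lower and 0 higher adjusted over the list alone (camera, adjusted p = 0.00789, and adjusted p = 0.189 with an estimated correlation).

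Among the other genes fixed for naming, BRD2, itself a BET gene, rose (0.93 ± 0.13), as did the anti-apoptotic gene MCL1 (0.89 ± 0.14). BRD3 (0.32), HDAC1 (0.09), HDAC2 (0.06), MYCN (0.21), BCL2L1 (-0.30), ATF4 (0.05), DDIT3 (-0.06), PPARGC1A (-0.59) and HK2 (-0.37) did not pass. PMAIP1 (1.2), SOX2 (0.55), HDAC3 (0.52) and OLIG2 (-0.56) passed with all arrays but lost the call when single arrays were left out. PMAIP1 lost it without OTX015 replicate 1 (adjusted p = 0.0567). SOX2 lost it without DMSO replicate 2 or either OTX015 array (adjusted p = 0.0743 to 0.0805), and HDAC3 without any 1 of the DMSO and OTX015 arrays (adjusted p = 0.0656 to 0.0999). OLIG2 kept it without OTX015 replicate 2 and lost it without any other array (adjusted p = 0.0548 to 0.217). The count of 3697 genes became 2391 without DMSO replicate 2, 1963 without OTX015 replicate 1 and 1885 without OTX015 replicate 2. Camera called 16 of 46 lists, and 4 lost the call in at least 1 of the 13 alternatives run on lists. With a correlation estimated per list, 0 calls held in any comparison.

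**Figure D1:**
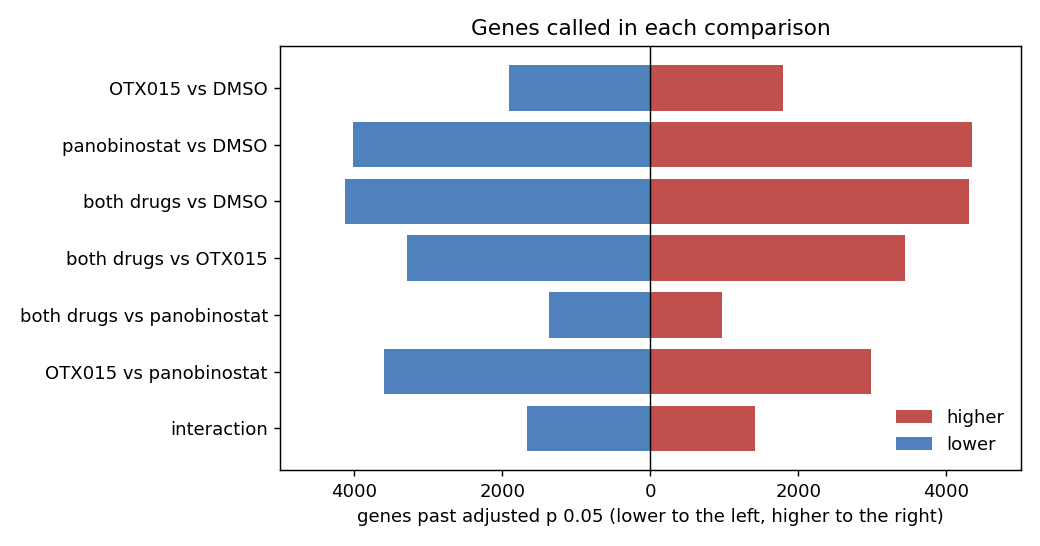
Number of genes that passed adjusted p under 0.05 in each of the 7 comparisons, with genes lower in the first-named group as bars to the left of 0 and genes higher as bars to the right. OTX015 alone changed 3697 genes against DMSO, panobinostat alone 8360 and the combination 8424.

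The HDAC inhibitor alone was compared with the same vehicle arrays. Panobinostat raised PAEP, which encodes the secreted lipocalin glycodelin, by at least 87.6-fold (7.46 ± 0.13, adjusted p = 7.09e-08), from a DMSO level of 2.02 that lay under background. It raised DHRS2, a dehydrogenase gene long known to respond to HDAC inhibitors, by 81.9-fold (6.36 ± 0.27). The paraspeckle RNA NEAT1 (5.94 ± 0.29), the small GTPase gene GEM (5.78 ± 0.24), GTSF1 (5.67 ± 0.33) and ZCCHC12 (5.15 ± 0.13) rose as well. RFPL4AL1 (6.32 ± 0.30) and USP17L5 (5.23 ± 0.15), whose near-identical copies an array may not separate, rose too. Of the genes that fell, TECRL (-5.69 ± 0.17), RHOJ (-5.16 ± 0.16), the neuronal membrane glycoprotein gene GPM6A (-4.62 ± 0.17) and SOX2-OT, a noncoding RNA that overlaps SOX2 (-4.54 ± 0.19), were among the largest. SOX10, the transcription factor that maintains oligodendrocyte identity, fell 34.8-fold (-5.12 ± 0.21), and ATP10B (-5.04 ± 0.18) and CA14 (-4.75 ± 0.26) fell here too. Under the background level in DMSO were also NEAT1, GTSF1, RFPL4AL1 and USP17L5, whose rises were at least 37.7-fold, 16.2-fold, 42.7-fold and 23.1-fold. RHOJ, SOX2-OT, ATP10B and CA14 averaged under it in panobinostat, with falls of at least 34.3-fold, 6.68-fold, 25.3-fold and 22.6-fold. In all, 8360 of 22458 genes passed, 4347 higher and 4013 lower.

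All 49 measured G2/M and mitosis genes were lower, with 49 lower and 0 higher adjusted over the list alone, under panobinostat, and their median was -2.59 (camera, adjusted p = 3.9e-29, and adjusted p = 0.112 with an estimated correlation). Cyclin A2 (CCNA2, -4.29 ± 0.23), FOXM1 (-4.07 ± 0.12), the mitotic kinase PLK1 (-4.05 ± 0.21) and the anaphase activator CDC20 (-3.64 ± 0.26) led them. Of 45 G1/S and DNA replication genes, 37 fell and 1 rose, with 38 lower and 1 higher adjusted over the list alone (camera, adjusted p = 1.97e-12, and adjusted p = 0.121 with an estimated correlation). Among them were thymidylate synthase (TYMS, -3.22 ± 0.13), cyclin D1 (CCND1, -3.11 ± 0.17) and the ribonucleotide reductase subunit RRM2 (-3.03 ± 0.18). Homologous recombination and Fanconi repair genes had 16 of 25 lower and 0 higher, with 16 lower and 0 higher adjusted over the list alone (camera, adjusted p = 5.5e-06, and adjusted p = 0.214 with an estimated correlation). These included FANCI (-2.66 ± 0.18) and EXO1 (-2.29 ± 0.14). MYC targets had 31 of 45 lower and 3 higher, with 31 lower and 4 higher adjusted over the list alone (camera, adjusted p = 7.14e-07, and adjusted p = 0.143 with an estimated correlation). MYC itself fell 7.06-fold (-2.82 ± 0.12), whereas ornithine decarboxylase (ODC1), a polyamine enzyme on the same list, rose (1.69 ± 0.13). Genes known to fall with BET inhibitors fell under the HDAC inhibitor as well, 9 of 14 lower and 0 higher, with 9 lower and 0 higher adjusted over the list alone (camera, adjusted p = 0.000894, and adjusted p = 0.121 with an estimated correlation). Cyclin D2 (CCND2, -2.07 ± 0.13) and CDK6 (-1.37 ± 0.16) were included. Pentose phosphate and nucleotide synthesis genes had 13 of 24 lower and 0 higher, with 13 lower and 0 higher adjusted over the list alone (camera, adjusted p = 0.000795, and adjusted p = 0.186 with an estimated correlation). In serine, glycine and one-carbon metabolism 13 of 20 fell and 2 rose, with 13 lower and 3 higher adjusted over the list alone (camera, adjusted p = 0.00695, and adjusted p = 0.354 with an estimated correlation). The transsulfuration enzyme CBS fell (-2.04 ± 0.13). Ribosomal protein genes had 13 of 42 lower and 0 higher, with 12 lower and 0 higher adjusted over the list alone (camera, adjusted p = 0.0039, and adjusted p = 0.433 with an estimated correlation).

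Oligodendrocyte lineage genes had 11 of 19 lower and 1 higher, with 12 lower and 1 higher adjusted over the list alone (camera, adjusted p = 0.000591, and adjusted p = 0.121 with an estimated correlation). NKX2-2 (-4.13 ± 0.23) and the receptor phosphatase gene PTPRZ1 (-3.9 ± 0.12) fell beside SOX10. Glioma stem and neural progenitor genes had 18 of 34 lower and 5 higher, with 19 lower and 6 higher adjusted over the list alone (camera, adjusted p = 0.00408, and adjusted p = 0.192 with an estimated correlation). OLIG1 (-3.73 ± 0.17), the Notch ligand DLL1 (-3.71 ± 0.18) and the surface marker PROM1 (-2.9 ± 0.18) fell, and the stem cell factor SOX2 fell 4.33-fold (-2.11 ± 0.12). Neuronal and synaptic genes had 20 of 42 higher and 8 lower, with 21 higher and 8 lower adjusted over the list alone (camera, adjusted p = 0.000526, and adjusted p = 0.112 with an estimated correlation). The largest were in synapsin (SYN1, 4.36 ± 0.17), beta-synuclein (SNCB, 3.98 ± 0.16) and the microtubule regulator STMN2 (3.35 ± 0.22). DLL1 was under background with panobinostat and STMN2 in DMSO, with changes of at least 11.8-fold and 5.83-fold.

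The list known to rise with HDAC inhibitors had 14 of 18 higher and 0 lower, with 15 higher and 0 lower adjusted over the list alone (camera, adjusted p = 1.24e-09, and adjusted p = 0.0989 with an estimated correlation). Among them were the metallothionein MT2A (4.88 ± 0.18), GADD45B (4.12 ± 0.15) and CDKN1A (3.47 ± 0.13). Immediate early genes had 16 of 20 higher and 2 lower, with 16 higher and 2 lower adjusted over the list alone (camera, adjusted p = 9.02e-07, and adjusted p = 0.274 with an estimated correlation). These included IER3 (4.41 ± 0.36), EGR1 (4.33 ± 0.25) and FOS (3.68 ± 0.28). Autophagy and lysosome genes had 21 of 32 higher and 0 lower, with 22 higher and 0 lower adjusted over the list alone (camera, adjusted p = 1.4e-08, and adjusted p = 0.0989 with an estimated correlation). Cathepsin B (CTSB) rose by 2.65 and WIPI1 by 2.42 on the log2 scale. Antigen presentation genes had 9 of 17 higher and 3 lower, with 9 higher and 4 lower adjusted over the list alone (camera, adjusted p = 0.014, and adjusted p = 0.214 with an estimated correlation). The largest rises were in class II genes, among them HLA-DPA1 (3.16 ± 0.13), HLA-DMA (2.76 ± 0.14) and HLA-DRA (2.48 ± 0.17), the last at least 3.45-fold from a DMSO level under background. On the lists of other cell types, 4 of 16 measured microglia and macrophage markers also rose (CD68, CSF1R, ITGAX and TMEM119), and the median change of the 16 was 0.12. Of the other lists of this kind, endothelial markers had 3 of 13 higher and 2 lower, pericyte and fibroblast markers 3 of 14 higher and 1 lower, and lymphocyte markers 1 of 13 higher and 0 lower. Of 24 p53 targets 13 rose and 5 fell, with 15 higher and 5 lower adjusted over the list alone (camera, adjusted p = 0.014, and adjusted p = 0.212 with an estimated correlation). The growth factor gene GDF15 rose (2.81 ± 0.22) and TP53I3 fell (-1.81 ± 0.17). NRF2 targets had 9 of 21 higher and 2 lower, with 10 higher and 3 lower adjusted over the list alone (camera, adjusted p = 0.0181, and adjusted p = 0.498 with an estimated correlation). SRXN1 rose (3.7 ± 0.16) and NQO1 fell (-2.12 ± 0.17).

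Of the remaining genes fixed for naming, the stress-response transcription factor DDIT3 rose 24.4-fold (4.61 ± 0.15). HDAC1 (1.06 ± 0.14), HDAC3 (1.52 ± 0.12), MCL1 (1.04 ± 0.14) and the mitochondrial coactivator PPARGC1A (1.94 ± 0.22) rose, and BRD3 (-0.66 ± 0.13), BCL2L1 (-0.66 ± 0.14) and hexokinase HK2 (-0.71 ± 0.14) fell. BRD2 (0.16), HDAC2 (-0.14), MYCN (-0.19), PMAIP1 (0.58), ATF4 (0.04) and OLIG2 (0.11) did not pass. HEXIM1 passed (0.67) but lost the call without DMSO replicate 2 or either panobinostat array (adjusted p = 0.0574 to 0.0774). Camera called 19 of 46 lists, and 17 of them were called in each of the 13 alternatives run on lists.

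**Figure D2:**
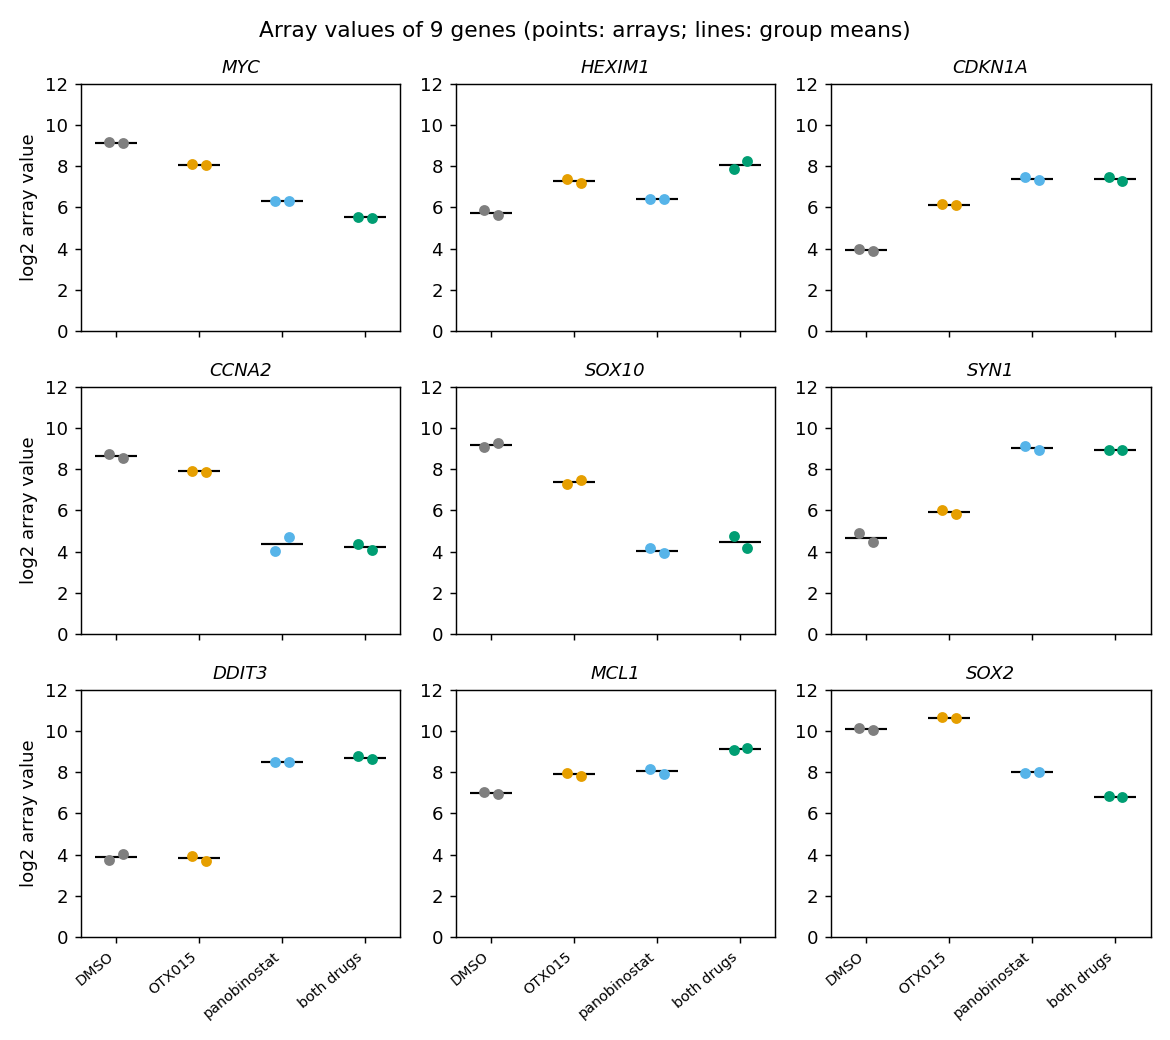
Log2 expression of MYC, HEXIM1, CDKN1A, CCNA2, SOX10, SYN1, DDIT3, MCL1 and SOX2 in each group, with each point 1 array and each line the mean of the 2 arrays of a group. MYC fell in each drug group, while DDIT3 rose under panobinostat and the combination and changed by -0.06 under OTX015.

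The combination was compared with vehicle to describe what both drugs did together. DHRS2 rose 172-fold (7.43 ± 0.27, adjusted p = 8.31e-07), PAEP at least 54.3-fold (6.77 ± 0.13), and the collagenase gene MMP1 at least 31.3-fold (5.7 ± 0.27), the last 2 from DMSO levels of 2.02 and 2.3 under background. The fatty acid hydroxylase gene CYP4F2 (5.64 ± 0.27), the neuronal kinase gene DCLK1 (5.47 ± 0.22) and the histone gene H2BC18 (5.78 ± 0.27) rose, with RFPL4AL1 (6.92 ± 0.30) and USP17L5 (6.67 ± 0.15). TECRL (-5.68 ± 0.17), RHOJ (-5.52 ± 0.16), GPM6A (-5.35 ± 0.17), ATP10B (-5.33 ± 0.18), the guidance cue SEMA3A (-5.14 ± 0.19), CHI3L2 (-5.12 ± 0.16) and PTPRZ1 (-5.06 ± 0.12) fell. CYP4F2, DCLK1, H2BC18, RFPL4AL1 and USP17L5 were under background in DMSO as well and rose at least 16.3-fold, 16.1-fold, 20.3-fold, 64.8-fold and 62.9-fold. RHOJ and ATP10B were under it in the combination and fell at least 34.3-fold and 25.3-fold. MYC fell (-3.62 ± 0.12), and HEXIM1 rose 4.96-fold (2.31 ± 0.17). In all, 8424 of 22458 genes passed, 4301 higher and 4123 lower.

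All 49 G2/M and mitosis genes fell, with 49 lower and 0 higher adjusted over the list alone and a median of -2.81 (camera, adjusted p = 1.4e-30, and adjusted p = 0.0951 with an estimated correlation). These included FOXM1 (-4.58 ± 0.12), CCNA2 (-4.42 ± 0.23) and the proliferation marker MKI67 (-4.28 ± 0.14). G1/S and DNA replication genes had 37 of 45 lower and 1 higher, with 41 lower and 1 higher adjusted over the list alone (camera, adjusted p = 8.34e-15, and adjusted p = 0.0986 with an estimated correlation). Among them were CCND1 (-3.83 ± 0.17), TYMS (-3.76 ± 0.13) and CCND2 (-2.98 ± 0.13). Homologous recombination and Fanconi genes had 17 of 25 lower and 0 higher, with 17 lower and 0 higher adjusted over the list alone (camera, adjusted p = 3.45e-07, and adjusted p = 0.189 with an estimated correlation). Pentose phosphate and nucleotide synthesis genes had 16 of 24 lower and 1 higher, with 17 lower and 1 higher adjusted over the list alone (camera, adjusted p = 1.05e-05, and adjusted p = 0.0986 with an estimated correlation). These included RRM2 (-2.67 ± 0.18) and the purine enzyme ATIC (-1.96 ± 0.16). MYC targets had 26 of 45 lower and 3 higher, with 28 lower and 3 higher adjusted over the list alone (camera, adjusted p = 3.02e-07, and adjusted p = 0.115 with an estimated correlation). Serine, glycine and one-carbon genes had 12 of 20 lower and 3 higher, with 12 lower and 3 higher adjusted over the list alone (camera, adjusted p = 0.00136, and adjusted p = 0.33 with an estimated correlation). Genes known to fall with BET inhibitors had 8 of 14 lower and 1 higher, with 8 lower and 1 higher adjusted over the list alone (camera, adjusted p = 0.000833, and adjusted p = 0.0986 with an estimated correlation).

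Oligodendrocyte lineage genes had 13 of 19 lower and 0 higher, with 13 lower and 0 higher adjusted over the list alone (camera, adjusted p = 1.22e-05, and adjusted p = 0.0951 with an estimated correlation). Among them were SOX10 (-4.68 ± 0.21) and the proteoglycan gene CSPG4 (-3.93 ± 0.18). Glioma stem and neural progenitor genes had 19 of 34 lower and 5 higher, with 20 lower and 5 higher adjusted over the list alone (camera, adjusted p = 0.000561, and adjusted p = 0.115 with an estimated correlation). The fatty acid binding protein FABP7 (-3.58 ± 0.17) and the transcription factor NFIB (-3.43 ± 0.12) fell, as did SOX2 (-3.29 ± 0.12). Receptor tyrosine kinase signalling genes had 11 of 27 lower and 4 higher, with 12 lower and 4 higher adjusted over the list alone (camera, adjusted p = 0.0278, and adjusted p = 0.33 with an estimated correlation). ERBB3 fell (-3.64 ± 0.16) and the phosphatase DUSP5 rose (3.14 ± 0.23). Neuronal and synaptic genes had 22 of 42 higher and 9 lower, with 23 higher and 9 lower adjusted over the list alone (camera, adjusted p = 0.00333, and adjusted p = 0.0986 with an estimated correlation). The RNA-binding protein gene ELAVL3 (4.56 ± 0.20), STMN2 (4.35 ± 0.22) and SYN1 (4.26 ± 0.17) rose most, STMN2 at least 11.6-fold from a DMSO level under background. Immediate early genes had 17 of 20 higher and 2 lower, with 17 higher and 2 lower adjusted over the list alone (camera, adjusted p = 4.31e-07, and adjusted p = 0.302 with an estimated correlation). These included EGR1 (4.47 ± 0.25) and FOS (4.19 ± 0.28). Autophagy and lysosome genes had 22 of 32 higher and 1 lower, with 24 higher and 1 lower adjusted over the list alone (camera, adjusted p = 1.92e-07, and adjusted p = 0.0861 with an estimated correlation). The list known to rise with HDAC inhibitors had 15 of 18 higher and 0 lower, with 15 higher and 0 lower adjusted over the list alone (camera, adjusted p = 2.29e-10, and adjusted p = 0.0861 with an estimated correlation). MT2A (5.39 ± 0.18) and GADD45B (4.26 ± 0.15) followed DHRS2 in size. Of 16 measured microglia and macrophage markers, 5 were higher and 0 lower, the 4 that rose under panobinostat and C1QA, which was under background in both groups and lost the call without DMSO replicate 1 or combination replicate 1 (adjusted p = 0.137 to 0.149). Endothelial markers had 2 higher and 1 lower, pericyte and fibroblast markers 3 and 2, and lymphocyte markers 0 and 0.

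BRD2 (1.6 ± 0.13), HDAC1 (0.77 ± 0.14), HDAC3 (1.68 ± 0.12), CDKN1A (3.46 ± 0.13), MCL1 (2.12 ± 0.14), ATF4 (0.73 ± 0.13), DDIT3 (4.83 ± 0.15) and PPARGC1A (1.82 ± 0.22) rose, and HK2 (-1.12 ± 0.14) and OLIG2 (-0.87 ± 0.15) fell. BRD3 (-0.22), MYCN (-0.16) and BCL2L1 (-0.08) did not pass. HDAC2 (-0.48) lost its call without DMSO replicate 1 or combination replicate 1 (adjusted p = 0.0523 to 0.0582). PMAIP1 (0.63) lost it without DMSO replicate 2 or any 1 of the OTX015 and combination arrays (adjusted p = 0.0676 to 0.24). Camera called 17 of 46 lists, of which 3 lost the call in at least 1 of the 13 alternatives run on lists.

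**Figure D3:**
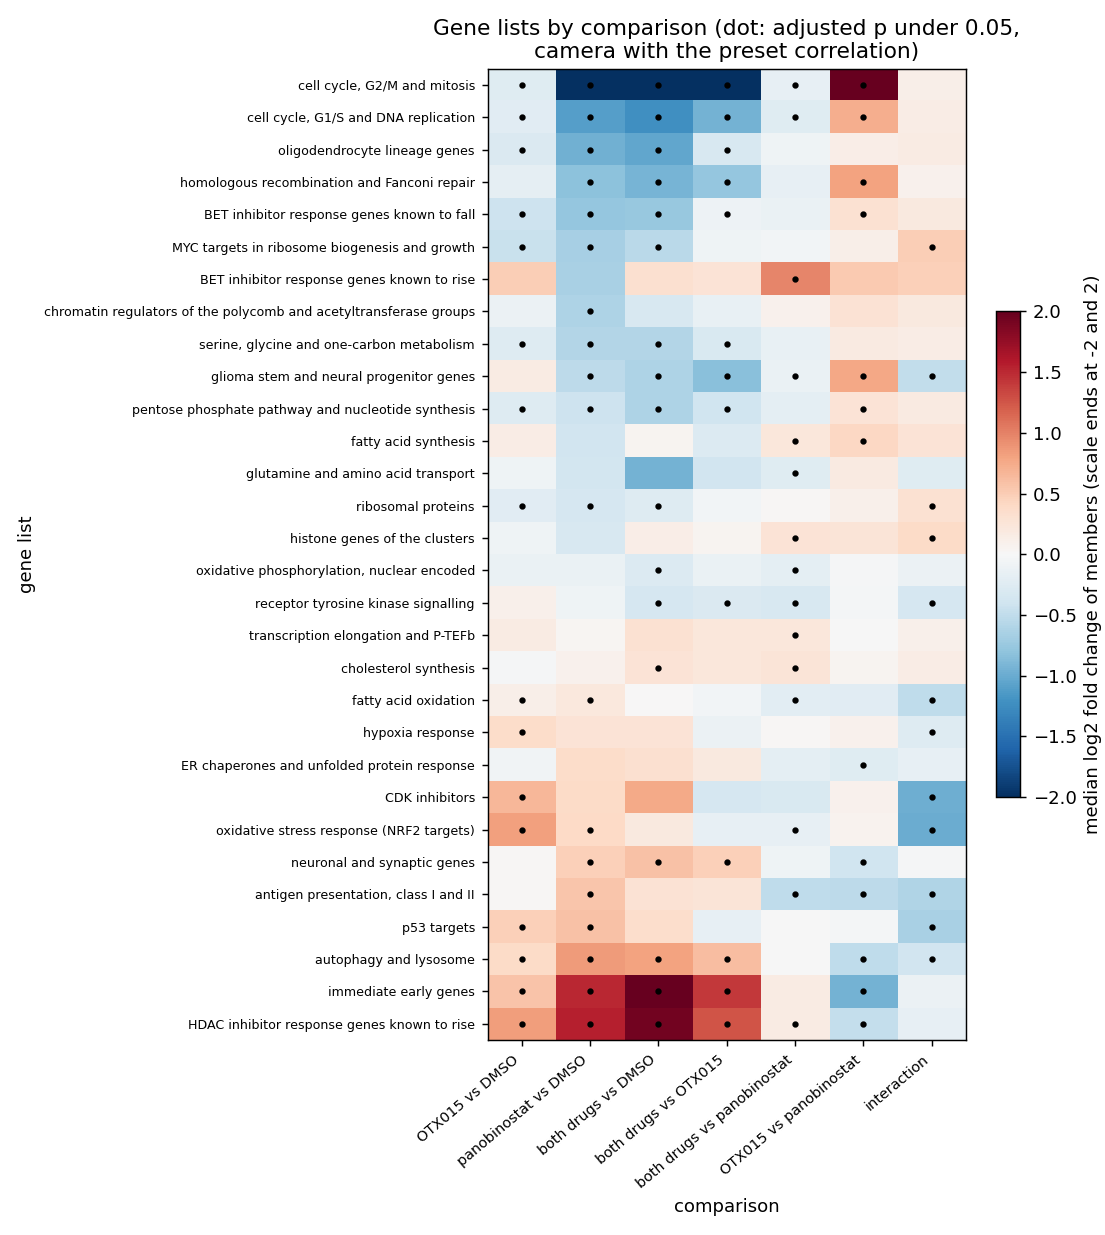
Median log2 fold change of the members of each gene list (one line of cells per list) in each comparison (columns), on a colour scale of log2 fold change, with a dot where camera with the preset correlation gave adjusted p under 0.05. The G2/M and mitosis list had a median of -0.25 under OTX015, -2.59 under panobinostat and -2.81 under the combination, each against DMSO, and 0 of the marked calls held with an estimated correlation.

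What panobinostat added to OTX015 was read from the combination against OTX015 alone. DHRS2 was 95.7-fold higher (6.58 ± 0.27, adjusted p = 2.29e-06), and PAEP (6.46 ± 0.13), MMP1 (6.03 ± 0.27) and CYP4F2 (5.61 ± 0.27) rose, as did RPL3L, a ribosomal protein gene expressed mainly in muscle (5.86 ± 0.21). The Notch target HES5 (-4.15 ± 0.30), the transcription factor SOX21 (-4.14 ± 0.18), GPM6A (-5.26 ± 0.17), PTPRZ1 (-5.25 ± 0.12), SEMA3A (-4.76 ± 0.19), PLPPR5 (-4.71 ± 0.28), the potassium channel subunit KCNE4 (-4.52 ± 0.23) and NQO1 (-4.3 ± 0.17) fell. PAEP, MMP1 and CYP4F2 were under background with OTX015 alone and rose at least 54.3-fold, 31.3-fold and 16.3-fold, and HES5, under it in the combination, fell at least 12-fold. In all, 6734 genes passed, 3442 higher and 3292 lower. All 49 G2/M and mitosis genes were lower, with 49 lower and 0 higher adjusted over the list alone (camera, adjusted p = 3.67e-37, and adjusted p = 0.0873 with an estimated correlation). Of 45 G1/S genes, 33 were lower and 0 higher, with 34 lower and 0 higher adjusted over the list alone (camera, adjusted p = 1.81e-13, and adjusted p = 0.123 with an estimated correlation). Homologous recombination and Fanconi genes had 16 of 25 lower and 0 higher, with 17 lower and 0 higher adjusted over the list alone (camera, adjusted p = 4.25e-08, and adjusted p = 0.18 with an estimated correlation). Glioma stem and neural progenitor genes had 19 of 34 lower and 3 higher, with 20 lower and 4 higher adjusted over the list alone (camera, adjusted p = 6.73e-07, and adjusted p = 0.0873 with an estimated correlation). SOX2 (-3.83 ± 0.12) and DLL1 (-3.68 ± 0.18) were included. Oligodendrocyte lineage genes had 9 of 19 lower and 2 higher, with 9 lower and 3 higher adjusted over the list alone (camera, adjusted p = 0.0046, and adjusted p = 0.153 with an estimated correlation).

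Neuronal and synaptic genes had 18 of 42 higher and 4 lower when panobinostat was added to OTX015, with 23 higher and 6 lower adjusted over the list alone (camera, adjusted p = 0.000423, and adjusted p = 0.0873 with an estimated correlation). Among them were ELAVL3 (4.67 ± 0.20) and INA (2.75 ± 0.28), which was under background with OTX015 alone and rose at least 3.78-fold. Immediate early genes had 14 of 20 higher and 1 lower, with 15 higher and 1 lower adjusted over the list alone (camera, adjusted p = 1.55e-06, and adjusted p = 0.273 with an estimated correlation). IER3 (4.69 ± 0.36) and ARC (3.34 ± 0.16) rose most. Autophagy and lysosome genes had 18 of 32 higher and 1 lower, with 20 higher and 2 lower adjusted over the list alone (camera, adjusted p = 8.5e-05, and adjusted p = 0.0873 with an estimated correlation). The list known to rise with HDAC inhibitors had 12 of 18 higher and 0 lower, with 13 higher and 1 lower adjusted over the list alone (camera, adjusted p = 4.3e-07, and adjusted p = 0.0873 with an estimated correlation). Among genes fixed for naming, BRD2 (0.67 ± 0.13), HDAC1 (0.68 ± 0.14), HDAC3 (1.16 ± 0.12), CDKN1A (1.27 ± 0.13), MCL1 (1.23 ± 0.14), ATF4 (0.68 ± 0.13), DDIT3 (4.89 ± 0.15) and PPARGC1A (2.42 ± 0.22) rose, and MYC (-2.55 ± 0.12), HDAC2 (-0.54 ± 0.12) and HK2 (-0.75 ± 0.14) fell. PPARGC1A was under background with OTX015 alone and rose at least 3.96-fold. MYCN (-0.38), BCL2L1 (0.22), PMAIP1 (-0.57) and OLIG2 (-0.32) did not pass. HEXIM1 (0.76) lost its call without OTX015 replicate 2 or combination replicate 2 (adjusted p = 0.0618 to 0.0686), and BRD3 (-0.54) without OTX015 replicate 1 or combination replicate 2 (adjusted p = 0.0894 to 0.0943). Camera called 13 lists. Centring each array on its median moved the median change of all genes by -0.106 and the share of called genes that were higher from 51.1% to 41%. Changes smaller than that shift have no settled direction, and no named gene or called list turned.

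What OTX015 added to panobinostat was a smaller set of changes, read from the combination against panobinostat alone. Histone genes of the replication-dependent clusters stood out: H4C4 rose 7.67-fold (2.94 ± 0.30, adjusted p = 0.00155), with H2BC21 (2.89 ± 0.21) and H3C1 (2.71 ± 0.31). H4C2 (2.96 ± 0.24) and H3C2 (3.46 ± 0.27), which averaged 3.01 and 1.22 under panobinostat, both under background, rose at least 7.67-fold and 3.13-fold. The zinc finger gene ZNF165 (2.99 ± 0.29), TMEM88 (2.78 ± 0.21) and RPL3L (2.77 ± 0.21) rose too. The tubulin gene TUBA1B (-2.57 ± 0.33), the integrin gene ITGB8 (-2.43 ± 0.18), SEMA3A (-2.21 ± 0.19), XIRP1 (-2.16 ± 0.14) and the protocadherin gene PCDHB14 (-2.07 ± 0.13) fell. TUBA1B and PCDHB14 were under background in the combination and fell at least 2.18-fold and 3.75-fold. In all, 2342 genes passed, 972 higher and 1370 lower. Of 44 histone genes, 16 rose and 1 fell, with 16 higher and 1 lower adjusted over the list alone (camera, adjusted p = 9.94e-06, and adjusted p = 0.251 with an estimated correlation). Of the 16, 4 averaged under background in at least 1 of the 2 groups. Genes known to rise with BET inhibitors, 5 of which are also on the histone list, had 5 of 9 higher and 1 lower, with 6 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.00413, and adjusted p = 0.251 with an estimated correlation). The histone list holds 4 of the genes that rose, so the 2 calls are not separate evidence. HEXIM1 rose 3.11-fold (1.64 ± 0.17), and the chromatin reader ZMYND8 fell (-1.85 ± 0.18).

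With OTX015 added, cholesterol synthesis genes had 5 of 18 higher and 0 lower, with 6 higher and 0 lower adjusted over the list alone (camera, adjusted p = 0.00189, and adjusted p = 0.421 with an estimated correlation). These included IDI1 (1.34 ± 0.16) and HMGCS1 (1.3 ± 0.16). Fatty acid synthesis genes had 7 of 18 higher and 1 lower, with 8 higher and 2 lower adjusted over the list alone (camera, adjusted p = 0.0115, and adjusted p = 0.274 with an estimated correlation). These included fatty acid synthase (FASN, 2.56-fold, adjusted p = 0.00272) and its regulator SREBF1 (1.57 ± 0.15). Antigen presentation genes had 8 of 17 lower and 0 higher, with 10 lower and 0 higher adjusted over the list alone (camera, adjusted p = 1.55e-05, and adjusted p = 0.251 with an estimated correlation). Among them were HLA-DMA (-1.29 ± 0.14) and HLA-DPA1 (-1.03 ± 0.13). Of the 16 microglia and macrophage markers, 0 were lower and 1 higher, CD68 (0.97), which lost the call without panobinostat replicate 2 or combination replicate 1 (adjusted p = 0.0754 to 0.0784). Receptor tyrosine kinase signalling genes had 9 of 27 lower and 0 higher, with 9 lower and 0 higher adjusted over the list alone (camera, adjusted p = 2.84e-05, and adjusted p = 0.251 with an estimated correlation). SPRY2 (-1.54 ± 0.19) and SPRED1 (-1.06 ± 0.12), feedback inhibitors of the pathway, were among those that fell. NRF2 targets had 7 of 21 lower and 0 higher, with 8 lower and 2 higher adjusted over the list alone (camera, adjusted p = 0.0115, and adjusted p = 0.534 with an estimated correlation). Glutathione reductase (GSR) was one of those that fell (-1.19 ± 0.14). MYC fell further (-0.80 ± 0.12), as did SOX2 (-1.17 ± 0.12), while BRD2 (1.43 ± 0.13) and MCL1 (1.07 ± 0.14) rose. BRD3 (0.44), HDAC1 (-0.29), HDAC2 (-0.34), HDAC3 (0.16), MYCN (0.03), CDKN1A (-0.01), PMAIP1 (0.05), DDIT3 (0.22), PPARGC1A (-0.12) and HK2 (-0.41) did not pass. BCL2L1 (0.57) lost its call without any 1 of the 6 drug-treated arrays (adjusted p = 0.0582 to 0.198), ATF4 (0.69) without any 1 of the panobinostat and combination arrays (adjusted p = 0.0584 to 0.105), and OLIG2 (-0.99) without panobinostat replicate 1 (adjusted p = 0.0566). The count of 2342 genes became 566 without panobinostat replicate 1, 767 without panobinostat replicate 2, 768 without combination replicate 1 and 1039 without combination replicate 2. Camera called 15 lists, 9 without panobinostat replicate 2, and 8 of the 15 lost the call in at least 1 of the 13 alternatives run on lists.

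The single drugs were also compared directly. GPM6A was 22.9-fold higher under OTX015 than under panobinostat (4.52 ± 0.17, adjusted p = 3.07e-06), and HES5 (4.34 ± 0.30), SOX21 (4.32 ± 0.18), DLL1 (4.19 ± 0.18), PTPRZ1 (4.1 ± 0.12) and NKX2-2 (3.85 ± 0.23) were higher as well. PAEP (-7.15 ± 0.13), DHRS2 (-5.51 ± 0.27), the lysophospholipase gene ENPP2 (-5.37 ± 0.16), IER3 (-5.32 ± 0.36), the integrin gene ITGAX (-5.2 ± 0.28), GTSF1 (-5.2 ± 0.33) and GEM (-5.03 ± 0.24) were lower under OTX015. HES5 and DLL1, under background with panobinostat, were at least 12-fold and 16.4-fold higher, and PAEP, ITGAX and GTSF1, under it with OTX015, at least 87.6-fold, 32.8-fold and 16.2-fold lower. In all, 6582 genes passed, 2979 higher and 3603 lower under OTX015. All 49 G2/M and mitosis genes were higher under OTX015, with 49 higher and 0 lower adjusted over the list alone (camera, adjusted p = 1.18e-35, and adjusted p = 0.102 with an estimated correlation). Of 45 G1/S genes, 34 were higher and 3 lower, with 34 higher and 3 lower adjusted over the list alone (camera, adjusted p = 1.22e-10, and adjusted p = 0.182 with an estimated correlation). Homologous recombination and Fanconi genes had 15 of 25 higher and 0 lower, with 18 higher and 0 lower adjusted over the list alone (camera, adjusted p = 1.4e-06, and adjusted p = 0.246 with an estimated correlation). For glioma stem and neural progenitor genes the counts were 19 of 34 higher and 4 lower, with 20 higher and 6 lower adjusted over the list alone (camera, adjusted p = 2.65e-05, and adjusted p = 0.133 with an estimated correlation). Fatty acid synthesis genes had 8 of 18 higher and 3 lower, with 10 higher and 4 lower adjusted over the list alone (camera, adjusted p = 0.015, and adjusted p = 0.192 with an estimated correlation). FASN was 7.13-fold higher (2.83 ± 0.16), and the elongase gene ELOVL2 was lower (-2.46 ± 0.20).

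Neuronal and synaptic genes were lower under OTX015 than under panobinostat in 20 of 42 cases and higher in 4, with 20 lower and 5 higher adjusted over the list alone (camera, adjusted p = 7.55e-05, and adjusted p = 0.102 with an estimated correlation). Immediate early genes had 15 of 20 lower and 2 higher, with 16 lower and 2 higher adjusted over the list alone (camera, adjusted p = 1.4e-05, and adjusted p = 0.312 with an estimated correlation). Autophagy and lysosome genes had 17 of 32 lower and 0 higher, with 17 lower and 0 higher adjusted over the list alone (camera, adjusted p = 1.26e-05, and adjusted p = 0.102 with an estimated correlation). Of 17 antigen presentation genes, 8 were lower and 2 higher, with 9 lower and 2 higher adjusted over the list alone (camera, adjusted p = 0.00175, and adjusted p = 0.191 with an estimated correlation). The list known to rise with HDAC inhibitors had 9 of 18 lower and 1 higher, with 9 lower and 1 higher adjusted over the list alone (camera, adjusted p = 2.65e-05, and adjusted p = 0.133 with an estimated correlation). Of genes fixed for naming, BRD2 (0.77 ± 0.13), BRD3 (0.98 ± 0.13), HEXIM1 (0.88 ± 0.17), MYC (1.75 ± 0.12) and SOX2 (2.66 ± 0.12) were higher under OTX015, and HDAC1 (-0.97 ± 0.14), HDAC3 (-1.0 ± 0.12), CDKN1A (-1.28 ± 0.13), DDIT3 (-4.67 ± 0.15) and PPARGC1A (-2.54 ± 0.22) lower, PPARGC1A at least 4.3-fold from an OTX015 level under background. HDAC2 (0.19), MYCN (0.41), BCL2L1 (0.35), MCL1 (-0.15), PMAIP1 (0.61), ATF4 (0.01) and HK2 (0.34) did not pass, and OLIG2 (-0.67) lost its call without OTX015 replicate 1 or panobinostat replicate 1 (adjusted p = 0.0631 to 0.0738). Camera called 13 lists. Centring each array on its median moved the median change of all genes by 0.128 and the share of called genes that were higher from 45.3% to 59.6%, and no named gene or called list turned.

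The design also allows a test of whether the drugs added up. The interaction is the log2 change under the combination minus the sum of the log2 changes under each drug alone, and 3086 genes passed, 1419 above the sum and 1667 below it. FRG2DP (4.18 ± 0.24), CA14 (3.98 ± 0.36), ATP10B (3.78 ± 0.26) and RLBP1 (3.66 ± 0.19), each lowered by both drugs, stood above the sum. In the combination they averaged 2.91, 2.71, 2.35 and 3.46, the first 3 under background (3.03) there and with panobinostat. For each, the sum predicted a level under background, so neither sign nor size is settled. SESN3, a stress-induced sestrin gene (-3.51 ± 0.20, adjusted p = 0.000442), SEMA3C (-3.38 ± 0.20), the glucose transporter SLC2A3 (-3.19 ± 0.29), CEMIP2 (-3.07 ± 0.21) and NEAT1 (-3.01 ± 0.40) stood below it. NEAT1 averaged 2.32 in DMSO, also under background. CDKN1A rose by 2.19 under OTX015, 3.47 under panobinostat and 3.46 under both, which left it below the sum (-2.21 ± 0.19). For MYC the drugs' effects differed from their sum by 0.27 (SE 0.16, adjusted p = 0.333) and for HEXIM1 by 0.09, neither of which passed.

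By median, NRF2 targets were of all lists the furthest below the sum, 12 of 21 below it and 0 above, with 12 lower and 0 higher adjusted over the list alone (camera, adjusted p = 1.43e-08, and adjusted p = 0.282 with an estimated correlation). Among them were SRXN1 (-2.29 ± 0.23), NQO1 (-2.18 ± 0.24) and TXNRD1 (-2.17 ± 0.19). p53 targets had 10 of 24 below and 2 above, with 14 lower and 2 higher adjusted over the list alone (camera, adjusted p = 0.000712, and adjusted p = 0.243 with an estimated correlation). These included TP53INP1 (-1.88 ± 0.28) and the ribonucleotide reductase subunit RRM2B (-1.59 ± 0.23). Autophagy and lysosome genes had 8 of 32 below and 0 above, with 10 lower and 0 higher adjusted over the list alone (camera, adjusted p = 0.00265, and adjusted p = 0.243 with an estimated correlation). CDK inhibitors had 4 of 7 below and 1 above, with 5 lower and 1 higher adjusted over the list alone (camera, adjusted p = 0.00333, and adjusted p = 0.243 with an estimated correlation). Fatty acid oxidation genes had 2 of 21 below and 1 above, with 5 lower and 1 higher adjusted over the list alone (camera, adjusted p = 0.000712, and adjusted p = 0.243 with an estimated correlation). MYC targets had 14 of 45 above the sum and 1 below, with 18 higher and 1 lower adjusted over the list alone (camera, adjusted p = 7.29e-06, and adjusted p = 0.243 with an estimated correlation). TCOF1 (2.01 ± 0.22) and SLC19A1 (1.65 ± 0.22) were included. Histone genes had 12 of 44 above and 2 below, with 13 higher and 2 lower adjusted over the list alone (camera, adjusted p = 0.000712, and adjusted p = 0.243 with an estimated correlation). H3C1 stood above the sum (3.02 ± 0.44). H3C2 did too (3.79 ± 0.38) but averaged 2.16 in DMSO, 1.83 under OTX015 and 1.22 under panobinostat, all under background, so the size of its interaction is not settled. Glioma stem and neural progenitor genes had 12 of 34 below and 3 above, with 14 lower and 4 higher adjusted over the list alone (camera, adjusted p = 0.0041, and adjusted p = 0.243 with an estimated correlation). SOX2 changed by 0.55 under OTX015, -2.11 under panobinostat and -3.29 under both, an interaction of -1.72 ± 0.17. Receptor tyrosine kinase signalling genes had 8 of 27 below and 1 above, with 8 lower and 1 higher adjusted over the list alone (camera, adjusted p = 0.00753, and adjusted p = 0.282 with an estimated correlation). The phosphatase DUSP6 stood below the sum (-2.75 ± 0.23) and ERBB3 above it (2.13 ± 0.23).

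BRD2 (0.50), BRD3 (0.11), HDAC1 (-0.38), HDAC2 (-0.40), HDAC3 (-0.36), MYCN (-0.19), MCL1 (0.19), ATF4 (0.63), DDIT3 (0.29), PPARGC1A (0.47), HK2 (-0.04) and OLIG2 (-0.43) had interactions that did not pass. BCL2L1 (0.88) and PMAIP1 (-1.15) passed. BCL2L1 lost the call without DMSO replicate 1, either OTX015 array, panobinostat replicate 1 or combination replicate 2 (adjusted p = 0.0552 to 0.0843). PMAIP1 lost it without DMSO replicate 2, panobinostat replicate 1 or any 1 of the OTX015 and combination arrays (adjusted p = 0.0708 to 0.126). The count of 3086 became 1883 without OTX015 replicate 1, 1631 without OTX015 replicate 2, 1686 without panobinostat replicate 1, 1793 without panobinostat replicate 2 and 1852 without combination replicate 1. Camera called 12 lists, of which 3 lost the call in at least 1 of the 13 alternatives run on lists.

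Both single drugs changed 2803 genes, 2587 of them in the same direction, with 1210 higher and 1377 lower. A further 216 went opposite ways, a count that became 96 or 76 without DMSO replicate 1 or 2, 88 or 90 without OTX015 replicate 1 or 2 and 134 without panobinostat replicate 1 or 2. Independent lists of the same sizes would share 347 higher and 341 lower genes. Simulated unchanged groups set against the same vehicle arrays shared 0.02 higher and 0 lower genes on average over 50 simulations. The correlation across genes, which are not independent replicates, was 0.557 between the drugs' log2 fold changes and 0.499 in the simulations, and the covariance was 0.219 against 0.0171, a difference of 0.202. With 1 vehicle array for each drug, so that no control was shared, the correlation was 0.46 and 0.448 and the covariance 0.194 and 0.191 in the 2 possible assignments. Without DMSO replicate 2, OTX015 replicate 1 or OTX015 replicate 2, the count of genes higher under both became 761, 703 and 618. Without OTX015 replicate 1 or 2 the count lower under both became 791 and 813. For panobinostat and the combination, each against DMSO, 3325 genes were higher and 3132 lower in both, against 833 and 737 for independent lists, and the covariance was 0.672 against a simulated 0.0171. For OTX015 and the combination the shared counts were 1156 and 1449, against 343 and 350, with a covariance of 0.232 against 0.0172. The count of 1156 became 736 without DMSO replicate 2 and 657 or 601 without OTX015 replicate 1 or 2, and that of 1449 became 833 or 867 without OTX015 replicate 1 or 2. With separate vehicle arrays the covariance was 0.651 and 0.64 for the first of these pairs and 0.213 and 0.198 for the second.

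The combination passed both single drugs in the same direction for 1104 genes. This count became 312 or 396 without panobinostat replicate 1 or 2 and 421 or 550 without combination replicate 1 or 2. The interaction was called the same way for 469 of these genes, a count that became 275 without DMSO replicate 2, 285 or 245 without OTX015 replicate 1 or 2, 170 or 199 without panobinostat replicate 1 or 2 and 205 or 309 without combination replicate 1 or 2. Where both drugs had been called in one direction and the interaction was called, 1514 of 1520 genes moved less under the combination than the sum, 734 of them lowered by both drugs and 780 raised by both. Without OTX015 replicate 1 this became 879 of 882, without OTX015 replicate 2 759 of 760, without panobinostat replicate 1 914 of 917 and without panobinostat replicate 2 967 of 968.

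**Figure D4:**
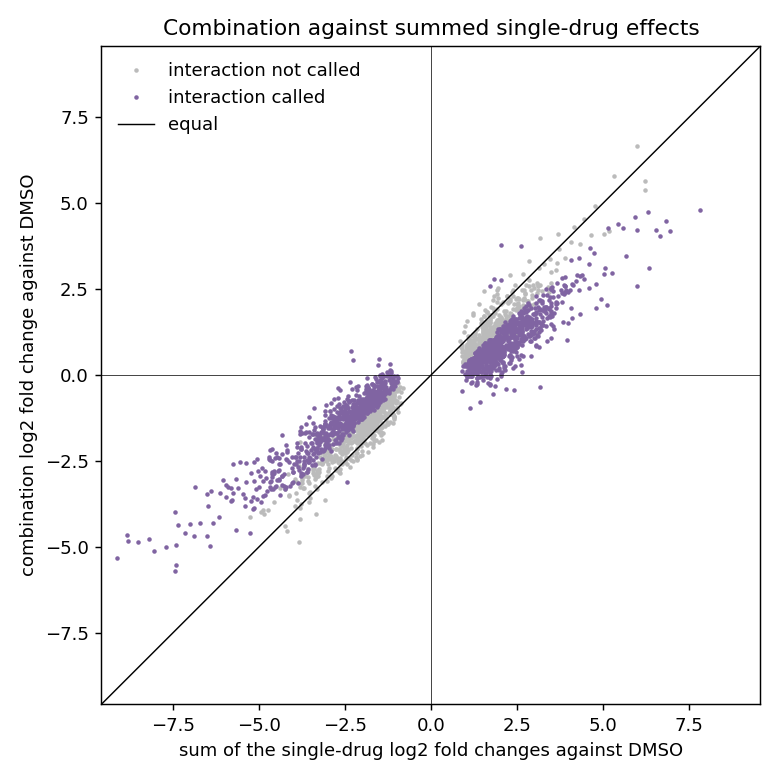
Log2 fold change under the combination (vertical axis) against the sum of the log2 fold changes under OTX015 and panobinostat (horizontal axis), each against DMSO, with 1 point for each of the 2587 genes called in the same direction under both drugs and a diagonal where the values are equal. Among genes with a called interaction, 1514 lie nearer to 0 than the diagonal.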

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

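The test of interaction signs on separate arrays was chosen after a simulation with additive effects had been seen. The wording that limits the floor and ceiling explanations to most of the genes was set after their values were seen. The genes named here were picked by their values, and the counts with arrays left out were added after the data were seen.

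The effect of OTX015 differed between cells without and with panobinostat. For 331 genes the drug had called effects in opposite directions in the 2 settings and a called interaction in limma. This count became 182 without DMSO replicate 2, 147 or 130 without OTX015 replicate 1 or 2, 69 or 107 without panobinostat replicate 1 or 2 and 97 or 139 without combination replicate 1 or 2. The interaction for SESN3, a sestrin of the stress response, was -3.51 (adjusted p = 0.000442), from 1.83 alone to -1.67 with panobinostat. The cytokine receptor gene LIFR (interaction -2.83) went from 1.49 to -1.34, and the guidance cue SEMA3C (interaction -3.38) from 2.04 to -1.34. ZNF217 (interaction -2.67) went from 1.37 to -1.29, the latter not called without panobinostat replicate 1 (adjusted p = 0.0522), and the histone demethylase gene KDM7A (interaction -2.91) from 1.63 to -1.29. The muscle enolase gene ENO3 (interaction 3.46) went the other way, from -1.34 to 2.12.

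Probe sets that the annotation did not list were outside the comparisons of the report. Of 1328 such probe sets, 140 (10.5%) passed for OTX015 against DMSO, 348 (26.2%) for panobinostat and 355 (26.7%) for the combination, with 71, 185 and 183 of them higher. The count for OTX015 became 80 or 65 without DMSO replicate 1 or 2 and 52 without OTX015 replicate 1 or 2.

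Genes that both drugs moved the same way changed less under the combination than the sum of the single effects, in 1514 of the 1520 such genes with a called interaction (879 of 882 and 759 of 760 without OTX015 replicate 1 or 2, 914 of 917 and 967 of 968 without panobinostat replicate 1 or 2). An array floor in most of the 734 lowered genes was argued against by their combination levels. The median was 4.71, and 16.9% (95% exact binomial interval 14.3 to 19.8) lay at or below background (3.03). However, 41% had an additive prediction that low. For genes at background (FRG2DP, CA14 and ATP10B among them) the floor stays open. A ceiling at 9.62 (99th percentile of all group means) was argued against in most of the 780 raised genes. Their combination median was 6.79, 3.59% (2.4 to 5.15) reached 9.62 and 12.9% were predicted to. A lower ceiling stays open. Noise shared by the interaction and the summed effects was argued against by genes picked on one array of each group and tested on the other: 90.4% of 823 genes, and 94.2% of 832 with the arrays exchanged, had an interaction opposite in sign, and 20 simulations with additive effects gave 0 to 2 called interactions against 3086. A hypothesis that remains open and untested is that the drugs may act on overlapping targets, each already near its full effect at 5 µM, which 1 dose and 1 time cannot separate from other causes.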

How the results depend on the processing

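The alternative with 1 vehicle array for each drug, and all reruns of the counts of genes by how treatments compare, of unlisted probe sets and of families, were chosen after the data were seen, and the others before. None of those run on lists or named genes turned a called list or a named gene. The replicate block and leaving out an array of a group not compared cannot change a fold change. Of 16351 comparisons of 1364 named gene values with the alternatives, 15287 kept their side of the threshold, 1021 lost a call and 43 gained one. The cause was not tested for the changes below, except where fewer arrays, fewer genes or a stricter threshold make it plain. Of 105 list calls with the preset correlation, 81 were kept in each of the 13 alternatives run on lists with that correlation (scaling, the low-gene filter, array weights, the replicate block and each array left out), 24 were lost in at least 1, and 73 had adjusted p under 0.01. The fits of only the groups compared, with an intensity trend and on all probe sets were not run on lists. With a correlation estimated per list, 0 lists were called in any comparison.

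For the combination against panobinostat, 9 lists were called after quantile normalization and 9 with the lowest 25% of genes left out, against 15, and a fit of only the groups compared called 1477 genes against 2342. At adjusted p under 0.01 the counts became 1739 for OTX015 against DMSO, 4455 for the combination against OTX015, 622 for the combination against panobinostat, 4272 for OTX015 against panobinostat and 1145 for the interaction. With a minimum change of 2-fold, that is 1 on the log2 scale, they became 1011, 3764, 3923, 2712, 529, 2580 and 1786 in the order of the comparisons. The covariance of the single drugs' changes became 0.278 with the lowest 25% of genes left out, against 0.219.

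Leaving out 1 array gave between 1885 (without OTX015 replicate 2) and 3415 genes for OTX015 against DMSO, whose main count was 3697, with 2391 without DMSO replicate 2 and 1963 without OTX015 replicate 1. For the combination against panobinostat it gave between 566 (without panobinostat replicate 1) and 2251 against 2342, with 767 without panobinostat replicate 2, 768 without combination replicate 1 and 1039 without combination replicate 2. For the interaction it gave between 1631 (without OTX015 replicate 2) and 2546 against 3086, with 1883 without OTX015 replicate 1, 1686 without panobinostat replicate 1, 1793 without panobinostat replicate 2 and 1852 without combination replicate 1. The counts of the other comparisons stayed within 1.5 times, between 6604 and 8240 for panobinostat, 7023 and 8063 for the combination, 4879 and 6824 for the combination against OTX015, and 4695 and 6658 for OTX015 against panobinostat. Called lists numbered between 13 and 16, 17 and 20, 15 and 17, 12 and 15, 9 (without panobinostat replicate 2) and 15, 10 and 16, and 10 and 14. Between the single drugs the correlation lay between 0.533 and 0.581 and the covariance between 0.217 and 0.246. Genes higher under both numbered between 618 (without OTX015 replicate 2) and 1119 against 1210, with 761 without DMSO replicate 2 and 703 without OTX015 replicate 1, and genes lower under both between 791 (without OTX015 replicate 1) and 1314 against 1377, with 813 without OTX015 replicate 2.

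With 1 array left out, genes changed in opposite directions by the single drugs numbered between 76 and 186 against 216, genes past both drugs in the combination between 312 and 1001 against 1104, and those with the interaction called the same way between 170 and 325 against 469. Genes called one way under both drugs with a called interaction numbered between 760 and 1203 against 1520, of which between 759 and 1198 moved less than the sum, against 1514. Genes with opposite OTX015 effects without and with panobinostat numbered between 69 and 239 against 331. Under OTX015 and the combination, between 601 and 1001 genes were higher, against 1156, and between 833 and 1306 lower, against 1449. Unlisted probe sets called for OTX015 numbered between 52 and 106 against 140. Scaling, the low-gene filter and the replicate block moved none of these gene counts by over 1.5 times, nor did any left-out array those shared by panobinostat and the combination.

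With OTX015 set against vehicle array 1 and panobinostat against vehicle array 2, the single drugs' changes had a correlation of 0.46 and a covariance of 0.194, with 716 genes higher and 890 lower under both. The reverse gave 0.448, 0.191, 805 and 863.

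The replicate numbers did not show a pairing by themselves: deviations of same-numbered arrays correlated at 0.047 to 0.118 across genes, and with 2 numbers this settles nothing. With the replicate number as a block, 3752, 8539, 8601, 6858, 2365, 6706 and 3172 genes were called in the order of the comparisons, and 16, 18, 17, 12, 15, 12 and 13 lists. The block gave a correlation of 0.557, a covariance of 0.219, and 1224 genes higher and 1423 lower under both drugs. The mean of a gene's probe sets, planned as an alternative, was not run because each gene has 1 probe set. Signal over background limits low genes, since changes of genes near the background level of 3.03 are compressed.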

Other observations

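The test of macrophage markers, which replaced 2 earlier forms, the test of S phase genes, the reruns of families with arrays left out, the repeat of the histone family test above background and the grouping of genes by shared symbol stem were chosen after the result was seen.

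Genes were grouped by symbol stem, which gave 289 families of at least 10 measured members, and camera was run on them as on the lists. Under panobinostat the intraflagellar transport genes, which build cilia, rose in 17 of 19 cases with a median of 1.21 (camera, adjusted p = 1.24e-07, and adjusted p = 0.854 with an estimated correlation), including IFT70A (2.34 ± 0.13), IFT88 (1.88 ± 0.14) and IFT80 (1.79 ± 0.13). Genes of cilia and flagella associated proteins had 22 of 56 higher and 1 lower (camera, adjusted p = 0.0115, and adjusted p = 0.854 with an estimated correlation), CFAP70 among them (at least 2.67-fold, from a DMSO level under the background of 3.03). SOX transcription factor genes had 13 of 22 lower and 1 higher (camera, adjusted p = 0.00145, and adjusted p = 0.854 with an estimated correlation), SOX6 (-3.24 ± 0.18) and SOX5 (-2.32 ± 0.14) falling and SOX9 rising (1.26 ± 0.13). Splicing factors of the SRSF family had 9 of 13 lower and 0 higher (camera, adjusted p = 0.00483, and adjusted p = 0.854 with an estimated correlation), and MCM genes, mostly of the replicative helicase, 9 of 11 lower and 0 higher (camera, adjusted p = 0.00145, and adjusted p = 0.99 with an estimated correlation), MCM7 (-1.85 ± 0.12) and SRSF1 (-1.36 ± 0.15) among them.

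Under OTX015 the families that fell belonged to mitochondrial translation and import and to host genes of small nucleolar RNAs. Large-subunit mitochondrial ribosomal protein genes had 13 of 53 lower and 0 higher (camera, adjusted p = 0.00206, and adjusted p = 0.965 with an estimated correlation), MRPL3 (-1.35 ± 0.13) and MRPL15 (-1.35 ± 0.18) among them. Inner-membrane translocase genes had 6 of 15 lower and 0 higher (camera, adjusted p = 0.00755, and adjusted p = 0.965 with an estimated correlation). Small nucleolar RNA host genes had 9 of 21 lower and 0 higher (camera, adjusted p = 0.00206, and adjusted p = 0.965 with an estimated correlation), SNHG15 falling most (-1.48 ± 0.17), and in the interaction 9 of 21 stood above the sum and 0 below (camera, adjusted p = 0.00158, and adjusted p = 0.869 with an estimated correlation). Adding OTX015 to panobinostat lowered 6 of 19 clustered protocadherin beta genes and raised 0 (camera, adjusted p = 1.6e-05, and adjusted p = 0.956 with an estimated correlation), PCDHB3 (-1.28 ± 0.13) and PCDHB16 (at least 2.16-fold lower, to a level under background) among them. None of these family calls was lost or turned under median centring or quantile normalization. With 1 array left out, the calls of the large-subunit and translocase families were lost without DMSO replicate 1 (adjusted p = 0.0994 for both), and the others given here were kept.

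Panobinostat raised 4 of 16 measured markers of microglia and macrophages in a culture of a tumour line, CD68 (log2 level 5.53 in DMSO and 9.46 with panobinostat), CSF1R (3.52 and 5.87), ITGAX (2.95 and 8.06, at least 32.8-fold) and TMEM119 (2.08 and 3.3, at least 1.21-fold), and in the combination they averaged 10.44, 5.42, 7.6 and 3.42. Such cells, a candidate explanation, would raise all their abundant transcripts. The upper 95% bound of the change excluded a 2-fold rise for the other 12 markers (75%), with highest bounds of 0.57 (panobinostat) and 0.81 (combination). Among them, C1QB went from 3.71 to 3.5 and C1QC from 3.01 to 3.14 with panobinostat. TYROBP (2.68), FCER1G (1.56), CD14 (2.11), AIF1 (1.65), PTPRC (1.03) and C1QA (2.14) stayed under the background of 3.03. All 12 but C1QB averaged under it in DMSO, where changes are compressed, so such cells stay open, as in an earlier test. A hypothesis also open and untested is that the tumour cells may express the 4 genes after HDAC inhibition.

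Histone genes were higher in the combination than under panobinostat, 16 of 44 with 1 lower. The spread of members was 3.22, 4.59, 5.48 and 6.17 times their median standard error in the H2A, H2B, H3 and H4 families. It was at least 3.5 times among members above background in both groups. Signal shared between near-identical histone genes stays open, since it too can give members at different levels different folds. More cells in S phase, a candidate explanation, would raise G1/S and DNA replication genes, but their median was -0.24, with 2 of 45 higher and 10 lower. Also open and untested is the hypothesis that BET inhibition may alter histone transcript levels without a change in replication.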
